A study of Arabidopsis thaliana with 11 samples.

How the data were processed

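Root tip RNA of Arabidopsis thaliana was sequenced in 11 samples of 4 groups, all in the Col-0 background per the labels. The groups were wild-type Col-0 with 3 samples, crn-3 with 2, clv2-gabi with 3 and cle40-2 with 3. Plants were grown vertically under constant light at 21 °C on agar with 2.2 g/l Murashige and Skoog salts, 0.5 g/l MES and 10 g/l sucrose. Plant age and the length of root cut are not given in the sources used here. RNA was extracted with a Qiagen plant kit that included a DNase step, followed by a further DNase treatment, and libraries were made by standard Illumina methods, per the labels. The submitters' processing notes name CASAVA version 1.8.2, DESeq without a version and the genome build TAIR10. The aligner, the counting tool, its treatment of strand and of reads that match several genes, and the annotation are not given in the sources used here.

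The data used were 3 tables of the authors' own comparisons, each setting a mutant against Col-0 over the same 28495 genes. The values per group in these deposited tables were treated as scores: they are the authors' means of normalized read counts, rounded to whole numbers, so that they cannot enter a count model. The fold change in the deposited tables is the ratio of the mutant mean to the Col-0 mean, taken by the authors before rounding and printed to 2 decimals. Among genes with high means in both groups it differed from the ratio of the printed means by at most 0.00637. The adjusted p-value was deposited by the authors to 3 decimals, so a value printed as 0 means that it rounds to 0, and the method of adjustment is not given in the sources used here. The Col-0 means differed between tables by a constant factor, 1.08 in the clv2-gabi table and 1.08 in the cle40-2 table relative to the crn-3 table, so levels were set against Col-0 only within a table.

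No value per sample was used, because the tables hold group means only. No standard deviation, interval or leave-out of a replicate could therefore be computed for a gene, and a mean may rest on a single library. Depth per sample is unknown. The normalized means summed to 26708310 in Col-0 and 26459270 in crn-3 within the crn-3 table, to 28800590 and 28025463 in the clv2-gabi table, and to 28949816 and 28212541 in the cle40-2 table. The labels do not say whether samples of a group came from separate cultures, so the authors' p-values measure the spread between these samples, which may be technical.

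A gene was called changed at the authors' adjusted p under 0.05. Of the 28495 genes, 22793 had an adjusted p in the crn-3 table, 22987 in the clv2-gabi table and 23602 in the cle40-2 table. The spread of fold changes was described by the central 95% over all genes at a similar mean. It holds real changes as well as error, and so does not measure the error of a single gene. For lists, correlations and position, log2 changes were computed as log2((mutant mean + 1) / (Col-0 mean + 1)), which understates the change of genes with low means.

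The groups, the lists, the threshold, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule named CLE40, CLV2 and CRN whatever their values, the 10 largest rises and 10 largest falls per mutant among called genes with a mean of at least 50 in the higher group, up to 4 called members per list with the smallest adjusted p, and up to 5 genes per direction called in both of a pair of mutants. Ties in the printed adjusted p went to the larger fold change. CLE peptides and root stem cell regulators could be named whatever their values. The result of 1 endodermis gene that the rule would name is not reported here. Of the gene identifiers, 28008 matched a locus of the TAIR10.1 annotation, from which symbols, product names and coordinates were taken, and 487 did not. The tables carry no coordinates, so every position given is that of TAIR10.1.

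The lists were 21 groups of genes: the mutated genes, CLE peptides, CLE receptors and root stem cell regulators, root cap, epidermis and root hair, xylem, phloem and endodermis markers, mitotic genes, DNA replication and S phase genes, genes of auxin, cytokinin and of defence and jasmonate, genes of iron, phosphate and nitrate supply, of heat shock, touch and hypoxia, the circadian clock, and photosynthesis genes as a sign of green tissue. In all, 8 members whose identifier carried another symbol in the annotation were dropped. The planned list test took a signed z from unadjusted p-values, which the tables do not hold. In its place, the log2 change of each gene with a mean of at least 10 was divided by the robust spread (median absolute deviation) of genes at its mean level, in 50 bins of the mean, and tested with cameraPR of limma 3.58.1 in R 4.3.3 at a preset correlation of 0.01, two-sided. Lists with at least 5 such members were tested, and p was adjusted by Benjamini-Hochberg over the lists of a mutant. The percentile of each list's median among 10000 random lists matched on mean level stands beside it. A correlation between genes could not be estimated without values per sample, so 0.05 was tried instead. Neither could counts adjusted over the list alone be given. Lists were also compared between mutants on the ratio of mutant means, rescaled by the Col-0 totals, a test chosen after seeing the data.

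Overlaps of calls were set against the number that independent lists would share and against 100 simulated data sets without effects, in which both mutants were compared with the same simulated controls. The simulated noise came from the spread of log2 changes in the crn-3 table, which also holds any real change and so tends to be too wide. In each simulated data set the genes with the most extreme values were taken. Their number per direction was that of called genes with a mean of at least 10 in both tables of the pair. The observed overlaps also count called genes with lower means, so the sets differ in size. The same data sets gave the simulated correlations and where genes called in a mutant lay in another. On simulated data for the crn-3 comparison with 18117 genes, the list test recovered 100.0% of lists shifted by 0.25 on the log2 scale and called 1.0% of unshifted lists. Genes were simulated independently and all members of a list were shifted alike. These rates therefore do not hold for lists whose members vary together. A shared covariance of 0.02 simulated for the crn-3 and clv2-gabi comparisons over 18117 genes was estimated as 0.0200 with a standard deviation of 0.00071. Runs of neighbouring genes were sought with the largest median over 15 consecutive genes with a mean of at least 50, against 1000 permutations of gene order. The edges of a block were those giving the largest sum of log2 changes, each less a fixed offset and held within fixed bounds. Sequence uniqueness was the percent of 50-base windows in a gene's exons that occur at a single place in the TAIR10.1 genome. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

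The alternatives tried were adjusted p under 0.1 and under 0.01, a log2 fold change of at least 1 in size, fold changes re-centred on the median gene, a mean of at least 50, a preset correlation of 0.05 and ranks. Alternatives added after seeing the data left out genes with low means, genes of a chromosome 3 block, genes near 0 in Col-0 and the mutated genes themselves.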

Results

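The data described the root tip transcriptomes of 3 single mutants and of wild-type Col-0. The mutants concern peptide signalling in the root meristem: CLE40 encodes a small secreted peptide of the CLE family, CLV2 a receptor-like protein without a kinase domain, and CRN (CORYNE) a membrane-bound kinase-like partner of CLV2. The title of the series sets CLE40 against CRN and CLV2 in root meristem growth. Each mutant was compared with the same Col-0 samples, 3 libraries, against 2 of crn-3, 3 of clv2-gabi and 3 of cle40-2. All group means (normalised read counts), fold changes and adjusted p-values of single genes given here are values of the authors' deposited tables, which hold no value per sample. Depth per sample is therefore unknown. The central 95% of fold changes of genes with a mean between 50 and 200 ran from 0.65 to 1.37 in crn-3, from 0.56 to 1.40 in clv2-gabi and from 0.53 to 2.41 in cle40-2. For means of 1000 and above the ranges narrowed to 0.83 to 1.14, 0.79 to 1.16 and 0.77 to 1.31.

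The mutated genes were examined first. In the libraries labelled clv2-gabi, CLV2 (AT1G65380, TAIR10.1 chromosome 1, 24286742 to 24289329) was 21.44-fold higher than in Col-0 in the authors' deposited table, with means of 4248 and 198 and an adjusted p that rounds to 0. This direction goes against a loss of transcript, and the labels do not say what the allele does to the transcript. The adjacent gene AT1G65370 was 3.5-fold higher in the same libraries in the authors' deposited table, with means of 321 in Col-0 and 1123 in the mutant. CLV2 had a fold change of 1.12 in crn-3 and of 1.24 in cle40-2 in the authors' deposited tables, neither past the threshold. In the libraries labelled crn-3, CRN (AT5G13290, chromosome 5, 4252842 to 4255378) had a mean of 111 against 91 in Col-0 in the authors' deposited table (1.22-fold, adjusted p of 1). CLE40 (AT5G12990, chromosome 5, 4109234 to 4109784) had a mean of 1 in Col-0 and of 3 in the libraries labelled cle40-2 in the authors' deposited table (adjusted p = 0.923), too low to check that label. For none of the 3 mutants did the transcript of the mutated gene show a loss, and the directions below rest on the labels.

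The crn-3 comparison asks what changes in the root tip when CRN is mutated. Falls outnumbered rises, and a few of the genes that rose were close to 0 in Col-0. In the authors' deposited table the threshold was passed by 100 genes, 43 higher and 57 lower. Among the rises in the authors' deposited table, AT1G24388 went from a mean listed as 0 to 152 and AT5G39770 from 2 to 52. Per the authors' deposited table, MRD1 (AT1G53480) rose from 3 to 348, and its neighbour HEI10 (AT1G53490), which acts in meiotic crossover formation, rose 2.68-fold. AT5G15360 rose from 5 to 344, AT2G44370 5-fold, AT2G04050 3.7-fold, AT5G44440 3.18-fold, AT5G19100 2.64-fold and AT3G19430 2.63-fold in the authors' deposited table. Among the falls in the authors' deposited table were AT5G45428 to 0.24 of Col-0, RABH1e to 0.30, EXO70H6 to 0.37, the terpene synthase TPS-CIN to 0.39, AT4G30460 to 0.40 and the auxin-induced gene AIR1 to 0.41. AT5G01210 and AT3G21340 fell to 0.41, AT2G47540 to 0.43 and the peroxidase gene AT5G64100 to 0.44 in the authors' deposited table. None of the 50-base windows of TPS-CIN was unique in the genome, so its reads cannot be told from those of another locus.

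Of the fixed lists, 8 of 19 passed in crn-3 (limma cameraPR, Benjamini-Hochberg adjusted p). Medians and tests of a list are over its members with a mean of at least 10, and calls are over its members with an adjusted p in the authors' deposited table. Root cap markers were shifted upward (median 1.13-fold, cameraPR adjusted p = 1.58e-05), with 1 of 18 members called, the polygalacturonase gene RCPG at 1.73-fold in the authors' deposited table. Epidermis and root hair markers were shifted downward (median 0.856 of Col-0, cameraPR adjusted p = 0.0024), with PRP3, a root hair cell wall protein gene, at 0.44 in the authors' deposited table the only one of 16 called. Endodermis markers lay lower (median 0.754 of Col-0, cameraPR adjusted p = 0.0248) with none of 14 called. Too few of them had a mean of at least 50 for a test at that level. The central range of fold changes at means of 10 to 50 was wide in crn-3, from 0.48 to 1.87. Phosphate starvation genes lay lower (0.893 of Col-0, cameraPR adjusted p = 0.0176) with 1 of 16 called, the phosphate transporter gene PHT1;1 at 0.60 in the authors' deposited table, of whose windows 57.5% were unique. CLE receptors and root stem cell regulators (1.09-fold, cameraPR adjusted p = 0.0037), phloem markers (1.15-fold, cameraPR adjusted p = 0.0178), touch genes (1.18-fold, cameraPR adjusted p = 0.0178) and hypoxia genes (1.15-fold, cameraPR adjusted p = 0.0463) lay higher. In those lists the calls were 0 of 28, 0 of 18, 1 of 8 and 0 of 13, the call being the calmodulin-like gene TCH3 at 2.04-fold in the authors' deposited table. The cameraPR adjusted p of the other 11 lists ran from 0.0977 to 0.570, and 0 of 22 mitotic and 0 of 19 S phase genes were called. At a preset correlation of 0.05 the root cap and root hair lists passed and the other 6 did not (cameraPR adjusted p from 0.0533 to 0.0955). Of the calls, 12 were higher genes with a Col-0 mean of 2 or less. With a log2 fold change of at least 1 in size 53 genes remained, 34 of them higher, while with a mean of at least 50 there were 22 higher and 56 lower.

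The clv2-gabi comparison asks the same of CLV2. Fewer genes rose than fell, and root hair markers were among the falls. In the libraries labelled clv2-gabi, 434 genes passed the threshold in the authors' deposited table, 69 higher and 365 lower. In the authors' deposited table MRD1 rose from 3 to 1154 and HEI10 3.64-fold. The flowering repressor gene SVP rose 2.77-fold, AT5G21940 2.73-fold, AT3G15450 2.7-fold, AT3G44870 3-fold, AT5G65207 2.36-fold and the dormancy-associated gene DYL1 2.34-fold in the authors' deposited table. In the authors' deposited table the peroxidase gene AT1G05240 and the protein kinase gene AT2G41970 fell to 0.27 of Col-0, CID5 to 0.29, the xyloglucan-modifying enzyme gene XTH17 to 0.31, MES15 to 0.31 and AT1G30870 to 0.32. ROPGEF4, which acts in root hair growth, and the root hair expansin gene EXPA7 fell to 0.33, and GXM2 and AT4G14650 to 0.34, in the authors' deposited table. Only 41.1% of the windows of AT1G05240 were unique.

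In clv2-gabi 7 of 19 lists passed (limma cameraPR, Benjamini-Hochberg adjusted p). Epidermis and root hair markers were shifted downward, to a median of 0.666 of Col-0 (cameraPR adjusted p = 1.57e-05), and 5 of 16 fell. EXPA7, the root hair regulator gene RSL4 at 0.40, PRP3 at 0.43 and the NADPH oxidase gene RHD2 at 0.64 were among them in the authors' deposited table. Endodermis markers lay at 0.703 of Col-0 (cameraPR adjusted p = 0.0156) with none of 14 called. Too few of them had a mean of at least 50 for a test at that level. The central range of fold changes at means of 10 to 50 was wide in clv2-gabi, from 0.42 to 1.72. Xylem markers lay at 0.836 (cameraPR adjusted p = 0.0148) with 2 of 21 lower. These were XCP2 at 0.54 and the secondary wall cellulose synthase gene CESA8 at 0.28 in the authors' deposited table. Phosphate starvation genes lay at 0.888 (cameraPR adjusted p = 0.0164) with 2 of 16 lower, PHT1;1 at 0.65 and PHT1;4 at 0.66 in the authors' deposited table. Root cap markers lay at 1.08-fold (cameraPR adjusted p = 0.0148) with 1 of 18 called, RCPG at 1.74-fold in the authors' deposited table. Photosynthesis genes lay at 1.36-fold (cameraPR adjusted p = 0.00505) with 1 of 18 called, LHCA4 at 1.52-fold in the authors' deposited table. The list of CLE receptors and root stem cell regulators passed (cameraPR adjusted p = 9.06e-10) with CLV2 itself as its 1 call of 28, and did not pass when CLE40, CLV2 and CRN were left out together (cameraPR adjusted p = 0.0795). The auxin repressor gene IAA14 fell to 0.65 in the authors' deposited table, the 1 call of 30 auxin genes. The cameraPR adjusted p of the other 12 lists ran from 0.0893 to 0.822, with 0 of 22 mitotic and 0 of 19 S phase genes called. At a preset correlation of 0.05 the root hair, photosynthesis and stem cell lists passed, and the root cap, xylem, endodermis and phosphate lists each had a cameraPR adjusted p of 0.0588.

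The cle40-2 comparison asks what changes when CLE40 is mutated. It had more calls than the other comparisons, with endodermis and photosynthesis genes higher and some transcripts present that were near 0 in Col-0. In the libraries labelled cle40-2, 1216 genes passed in the authors' deposited table, 758 higher and 458 lower, of which 143 higher genes had a Col-0 mean of 2 or less. From a Col-0 mean listed as 0, the seed storage protein genes CRU3 and CRA1 reached 383 and 67, BGLU19 66, the anther gene ATA27 52, AT3G10950 50, and the chloroplast protein genes FBA2 68, LHCA2 60 and RBCS1A 54 in the authors' deposited table. From a Col-0 mean of 1, the light-harvesting genes LHB1B1 and LHCB2.1 reached 578 and 256 in the authors' deposited table, of whose windows 86.3% and 76.5% were unique. The largest falls in the authors' deposited table were PIN1AT, a peptidyl-prolyl isomerase gene, from 6888 to 458 (0.07 of Col-0), and the lectin gene JAL22 to 0.08. SR fell to 0.17, AT3G16370 and AT2G24800 to 0.18, AT3G29430 to 0.19, the asparaginase gene ASPGB1 and SCPL9 to 0.20, AT3G47650 to 0.21 and AT4G22214 to 0.22 in the authors' deposited table.

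In cle40-2 5 of 20 lists passed (limma cameraPR, Benjamini-Hochberg adjusted p). Endodermis markers were higher, at a median of 2.27-fold (cameraPR adjusted p = 3.70e-09), and 9 of 14 rose. The Casparian strip genes CASP2 at 3.43-fold, CASP1 at 3.27-fold and PER64 at 3.12-fold were among them in the authors' deposited table. Photosynthesis genes lay at 5.63-fold (cameraPR adjusted p = 7.21e-67), and 16 of 20 rose, including RBCS1A, RBCS1B from 0 to 43, LHCB2.2 from 0 to 18 and LHCA2 in the authors' deposited table. The filter for list members used the average of the Col-0 and mutant means, so members near 0 in Col-0 entered only through cle40-2. The photosynthesis test held 17 members in cle40-2, against 12 in crn-3 and 12 in clv2-gabi. This selection favours a rise in its median and test. Hypoxia genes lay at 1.43-fold (cameraPR adjusted p = 0.00336), with the sucrose synthase genes SUS4 at 18.98-fold and SUS1 at 2.09-fold and the fermentation gene PDC1 at 1.65-fold in the authors' deposited table, 3 of 13. Nitrate genes lay at 1.14-fold (cameraPR adjusted p = 0.0240), with NRT1.1 at 1.59-fold, AMT1;3 at 1.58-fold and NIA1 at 1.51-fold higher and LBD39 at 0.71 lower in the authors' deposited table, of 13. Defence and jasmonate genes lay at 1.22-fold (cameraPR adjusted p = 0.0240), with 2 of 19 called, LOX2 from 0 to 23 and CYP71A12 at 10.85-fold in the authors' deposited table. At a preset correlation of 0.05 the nitrate and defence lists had a cameraPR adjusted p of 0.0675 each and the other 3 passed. By ranks the hypoxia list did not pass either (cameraPR adjusted p = 0.0967), and it had too few members with a mean of at least 50 for a test.

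Lists that did not pass in cle40-2 held some called genes in the authors' deposited table. Of 16 epidermis and root hair markers 5 were higher and 1 lower (cameraPR adjusted p of the list = 0.379), with LRX1 at 2.36-fold, PRP3 at 2.03-fold, PRP1 at 2.69-fold and RHD2 at 1.45-fold in the authors' deposited table. Of 22 xylem markers 1 was higher, CTL2 at 5.78-fold, and 1 lower, FLA11 at 0.48 in the authors' deposited table (cameraPR adjusted p of the list = 0.839). Of 24 CLE peptide genes 2 rose, CLE5 at 2.52-fold and CLE41 at 2.22-fold in the authors' deposited table (cameraPR adjusted p of the list = 0.608). Of 28 receptors and stem cell regulators 1 rose, PLT3 at 1.40-fold in the authors' deposited table, while the quiescent centre gene WOX5 had means of 12 and 27 there without passing (deposited adjusted p = 0.262). Of 30 auxin genes 1 rose, the auxin response factor gene ARF5 at 1.73-fold, and 1 fell, PBP1 (AT5G54490) to 0.56, in the authors' deposited table. Of 22 cytokinin genes 1 was called, the response regulator gene ARR15, lower at 0.24 in the authors' deposited table. EXI1 of the root cap list fell to 0.47, PS2 of the phosphate list to 0.50, and F6H1 of the iron list and HSP17.4 of the heat shock list rose 1.59-fold and 3.17-fold, per the authors' deposited table. None of 22 mitotic genes, 19 S phase genes, 18 phloem markers, 8 touch genes or 11 clock genes was called. The cameraPR adjusted p of the 15 lists that did not pass ran from 0.226 to 0.891. For the CLE peptide, auxin, xylem and touch lists in cle40-2, and the nitrate list in clv2-gabi, the median, the mean and the test did not share a sign. The iron, cytokinin, circadian and defence lists had no call in crn-3 or clv2-gabi, and neither did the heat shock list, which had too few members there for a test.

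**Figure D1:**
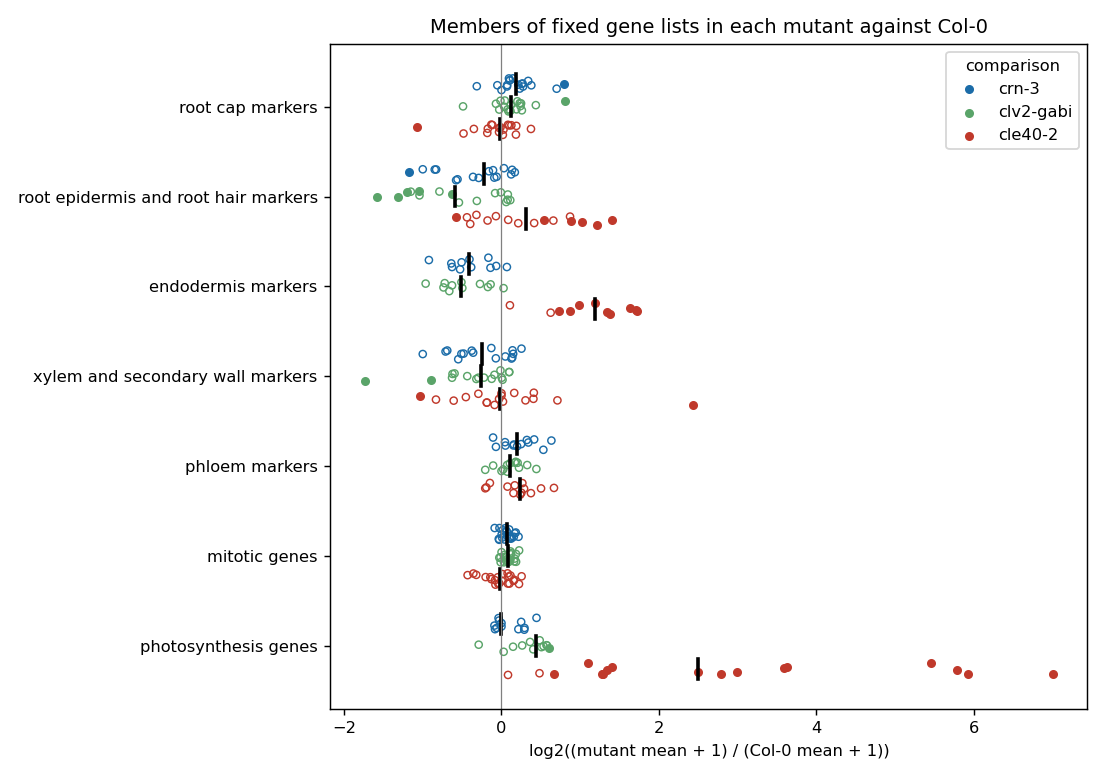
Log2 change of the members of 7 fixed gene lists against Col-0 in crn-3, clv2-gabi and cle40-2, for members with a mean of at least 10. Each point is a gene (filled where the authors' adjusted p is under 0.05) and black bars are list medians: the endodermis medians lie at -0.41, -0.51 and 1.18.

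The comparison of crn-3 with clv2-gabi asks whether the partners affect the same genes. Of the 57 genes lower in crn-3, 52 were also lower in the libraries labelled clv2-gabi, and of 41 higher genes tested in both 5 were higher in both. None went in opposite directions. The 5 were MRD1, HEI10, RCPG, AT5G52070 (1.76-fold in crn-3 and 1.65-fold in clv2-gabi) and AT3G15450 (1.54-fold and 2.7-fold) in the authors' deposited tables. MRD1 and HEI10 are neighbours on chromosome 1, so their rises may not be separate changes. Lower in both were AT4G30460 (0.40 and 0.36), AT2G47540 (0.43 and 0.36), AT5G64100 (0.44 and 0.40) and the neighbouring lipid-transfer type genes AT5G46900 (0.46 and 0.45) and AT5G46890 (0.47 and 0.43) in the authors' deposited tables. Independent lists would share 0.926 lower and 0.126 higher genes. Simulated groups without effects that share the Col-0 libraries gave a mean of 12.8 and at most 21 lower genes, and a mean of 2.04 and at most 5 higher genes. Across 18056 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.70, against 0.45 simulated, a Spearman rho of 0.65, against 0.42 simulated, and a covariance of 0.0439 against 0.0164 simulated. The shared controls could not be split between the comparisons. The size of the response was not tested between the mutants gene by gene.

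The comparison of cle40-2 with the other mutants asks whether the pathways act in opposite directions. Of 365 genes lower in the libraries labelled clv2-gabi, 46 were higher in cle40-2 and 31 were lower. Independent lists would share 11.8 and 7.36 genes, and simulated groups without effects gave means of 0.05 and 73.1. Lower in clv2-gabi and higher in cle40-2 in the authors' deposited tables were the root hair cellulase gene GH9C1 (0.42 and 2.12), PRP3 (0.43 and 2.03), the peroxidase gene AT1G30870 (0.32 and 1.86), the extensin gene HRGP1 (0.46 and 1.75) and the vacuolar aquaporin gene DELTA-TIP (0.57 and 1.74). Higher in clv2-gabi and lower in cle40-2 were 4 genes (1.39 if independent, 0 simulated), NSP1 (1.44 and 0.47), TAT3 (1.58 and 0.56), AT5G52070 (1.65 and 0.62) and AGL42 (1.52 and 0.35) in the authors' deposited tables. In both, 14 genes rose (2.24 if independent, a mean of 21.0 simulated without effects). Every simulated call is noise, so a count below the simulated mean does not by itself show opposition. Among the 14 were the asparagine synthetase gene ASN1 (8.2 and 8.02), PDX1.1 (1.83 and 1.86), SIS (1.74 and 2.36), CP5 (1.52 and 1.56) and AT3G60300 (1.45 and 1.59) in the authors' deposited tables. The 31 lower in both included NSP3 (0.40 and 0.22), AIR1 (0.43 and 0.37), AT5G24240 (0.41 and 0.43), AT1G24735 (0.47 and 0.45) and SQP2 (0.48 and 0.35) in the authors' deposited tables. In all 50 genes of this pair were called in opposite directions and 45 in the same direction, and at an adjusted p under 0.01 in both the counts were 22 and 24. Of the genes named here, DELTA-TIP, NSP1 and NSP3 lie in a chromosome 3 block described below, so their cle40-2 folds may follow from position.

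Between crn-3 and cle40-2, 9 genes were called in opposite directions and 14 in the same direction. The 6 genes lower in crn-3 and higher in cle40-2 included DELTA-TIP (0.61 and 1.74), the aquaporin gene PIP2E (0.53 and 1.59), PRP3 (0.44 and 2.03), AT5G64100 (0.44 and 1.52) and AT3G54580 (0.60 and 1.34) in the authors' deposited tables. DELTA-TIP lies in the chromosome 3 block, so its rise in cle40-2 may follow from position. AT5G47980 (1.87 and 0.50), AT5G19100 (2.64 and 0.54) and AT5G52070 (1.76 and 0.62) were higher in crn-3 and lower in cle40-2 in the authors' deposited tables. Higher in both were 7 genes, among them AT2G04050 (3.7 and 12.01), CRU3 (to means of 15 and 383), AT4G22753 (1.74 and 1.91), DOGT1 (2.22 and 2.21) and AT5G13210 (2 and 3.81) in the authors' deposited tables. Lower in both were 7, among them AT4G30460 (0.40 and 0.50), TPS-CIN (0.39 and 0.54), AT4G11210 (0.60 and 0.49), AIR1 (0.41 and 0.37) and OCT3 (0.57 and 0.33) in the authors' deposited tables. Independent lists would share 1.81 genes of the first kind, 0.833 of the second, 1.3 higher and 1.16 lower, and simulated groups without effects gave means of 0.02, 0, 7.04 and 14.4.

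Across genes, the log2 changes of cle40-2 had a Pearson r of 0.19 with those of crn-3, against 0.45 simulated without effects, and of 0.11 with those of clv2-gabi, against 0.50 simulated. Spearman's rho was 0.23 and 0.20, against 0.42 and 0.47 simulated. The covariance was 0.0160 with crn-3, against 0.0163 simulated, and 0.0104 with clv2-gabi, against 0.0162 simulated. The 362 genes called lower in clv2-gabi with a mean of at least 10 had a median fold of 0.685 in crn-3, where 98.9% of them lay below Col-0, and of 1.03 in cle40-2, where 45.6% did. Since these genes were picked as low against the same Col-0, simulated groups without effects also lay below it, at a median fold of 0.896 with 88.4% below in crn-3 and 0.897 with 91.6% below in cle40-2. The 673 such genes called higher in cle40-2 had a median fold of 1.02 in crn-3 and 1.00 in clv2-gabi, against 1.11 and 1.11 simulated. In cle40-2 only the medians of genes called in crn-3 lay near the simulated values. The median fold was 0.906 for those lower in crn-3 (0.886 simulated) and 1.14 for those higher (1.14 simulated). Of those lower in crn-3, 61.4% lay below Col-0 in cle40-2, against 93.1% simulated. Of those higher in crn-3, 27.0% lay below Col-0 in cle40-2, against 4.5% simulated. Both shares fell outside the range of the simulated data sets, so directions were more mixed than simulated. The simulated noise came from the crn-3 table, and fold changes spread more widely in cle40-2. At means of 50 to 200 their central range was 0.53 to 2.41 in cle40-2 and 0.65 to 1.37 in crn-3. A wider spread in cle40-2, or changes in the other mutants that cle40-2 lacks, would mix directions and lower r without opposition. These shares and the lower r therefore do not by themselves show opposition. At the median, endodermis markers were 3.83-fold lower in clv2-gabi than in cle40-2 (limma cameraPR on the ratio of mutant means, cameraPR adjusted p = 7.42e-11) and 3.53-fold lower in crn-3 than in cle40-2 (cameraPR adjusted p = 2.93e-12), with 11 of 11 members lower in each.

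**Figure D2:**
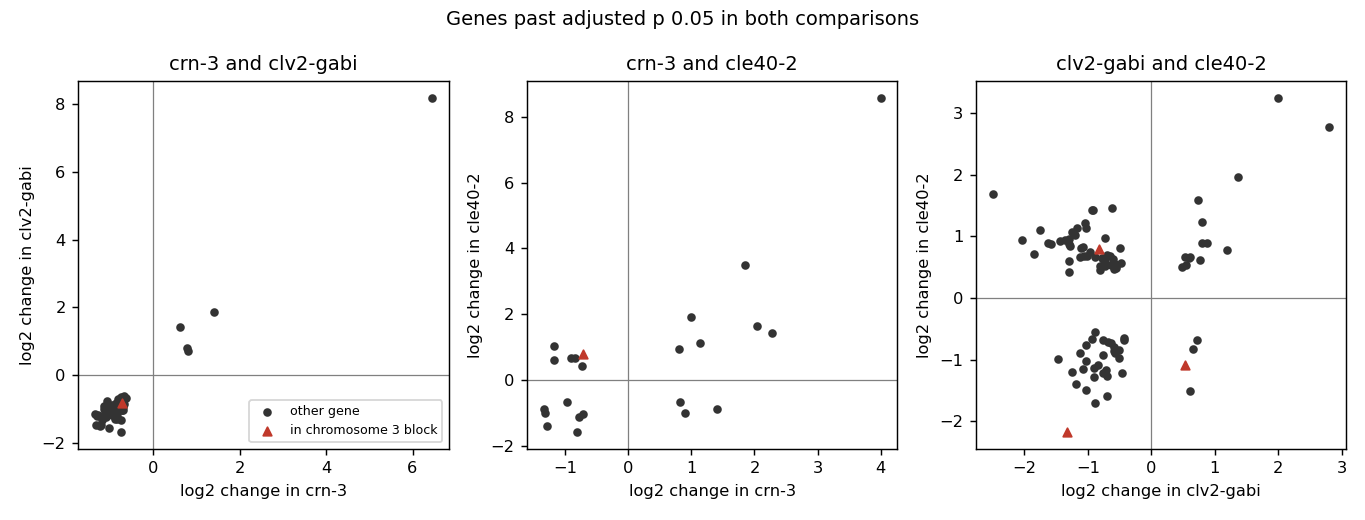
Log2 change of genes past the authors' adjusted p of 0.05 in both of a pair of comparisons, the first mutant on the x axis and the second on the y axis, with triangles for genes of a block on chromosome 3. The 57 genes of crn-3 and clv2-gabi lie in the same-direction quadrants, and of the genes of clv2-gabi and cle40-2 50 lie in the opposite quadrants and 45 in the same-direction ones.

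In cle40-2, 68 of the higher calls lay together on chromosome 3, between 5475855 and 5862437 (TAIR10.1), from AAE13 (AT3G16170) to TAS3 (AT3G17185). Of the 71 genes there with a mean of at least 50, 64 were higher and 3 lower, with a median fold of 1.92 and quartiles of 1.71 and 2.1 in the authors' deposited table. The 3 lower were AT3G16370, NSP3 and NSP1, and DELTA-TIP was among the higher. CTL2 lies in the block too, with lower means. The 50 genes before and the 50 after had median folds of 0.99 and 1.02 (1.015 in full). The nearest of those before the block was ASPGB1 (AT3G16150, start 5471735), which is among the largest falls in cle40-2. In the same block the median fold was 1.01 in crn-3 and 1.01 in clv2-gabi. The largest median over 15 neighbouring genes was 1.05 on the log2 scale in cle40-2, above the highest of 0.62 in 1000 permutations of gene order (permutation p = 0.001, the smallest they can give). In crn-3 and clv2-gabi it was 0.26 and 0.28 (permutation p = 0.007 and 0.005). Without the block 1145 genes remained called in cle40-2.

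**Figure D3:**
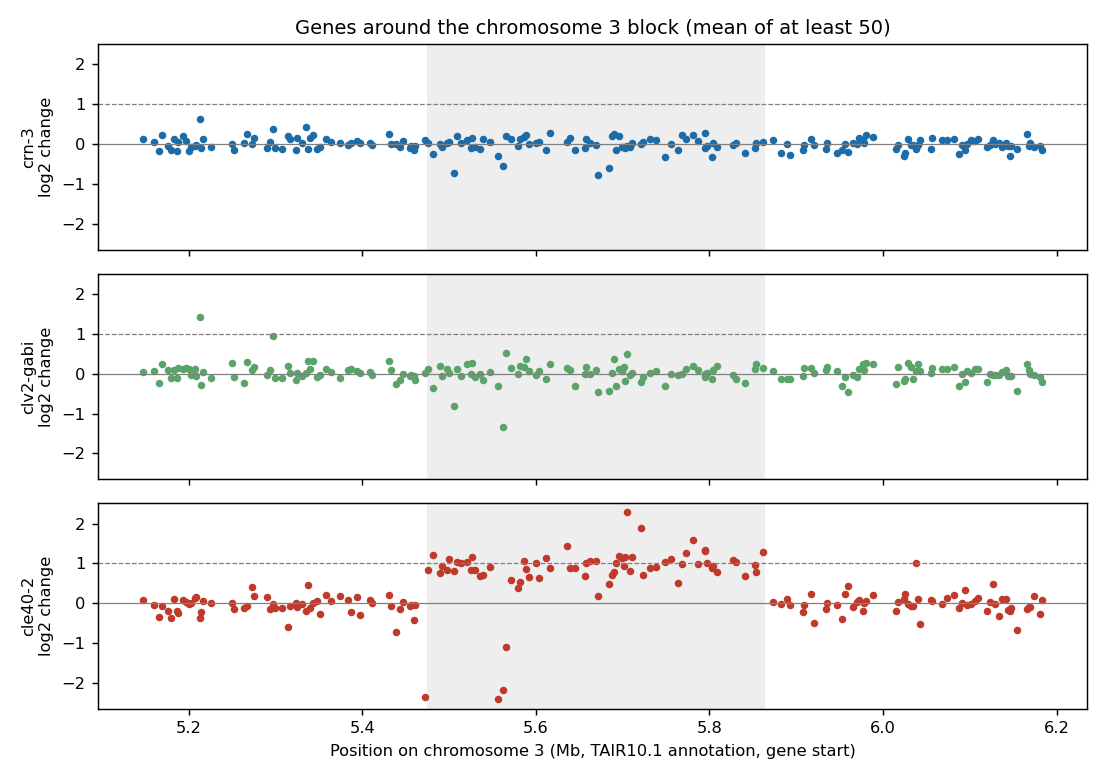
Log2 change against Col-0 of genes with a mean of at least 50 along chromosome 3 (gene start in Mb, TAIR10.1) in crn-3, clv2-gabi and cle40-2, with the block shaded and a dashed line at a doubling. In cle40-2 64 of 71 block genes were called higher, and the medians of the 50 genes on either side lie near 0.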

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

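All tests in this part were chosen after the result was seen. A list was picked out where its members differed between a pair of mutants in a test of the ratio of mutant means (limma cameraPR, Benjamini-Hochberg adjusted p), in which Col-0 enters only through the scaling of its totals. Against cle40-2, endodermis markers were lower in crn-3 (cameraPR adjusted p = 2.93e-12, 11 of 11 members) and in clv2-gabi (cameraPR adjusted p = 7.42e-11, 11 of 11). Epidermis and root hair markers were lower in crn-3 (1.44-fold, cameraPR adjusted p = 0.00305, 10 of 16) and in clv2-gabi (2.09-fold, cameraPR adjusted p = 0.000309, 10 of 16). Photosynthesis genes were lower in crn-3 (5.60-fold, cameraPR adjusted p = 1.03e-55, 17 of 17) and in clv2-gabi (4.37-fold, cameraPR adjusted p = 6.98e-27, 15 of 17). Members entered on the average of the mutant means compared, so some photosynthesis genes did so only through their high cle40-2 values. Root cap markers were higher in crn-3 (1.15-fold, cameraPR adjusted p = 0.00187, 15 of 18) and in clv2-gabi (1.11-fold, cameraPR adjusted p = 0.0317, 15 of 18). Defence and jasmonate genes were lower in clv2-gabi than in cle40-2 (1.40-fold, cameraPR adjusted p = 0.00685, 9 of 10), as were nitrate genes (1.18-fold, cameraPR adjusted p = 0.0403, 8 of 9) and hypoxia genes (1.19-fold, cameraPR adjusted p = 0.0317, 7 of 10). Between crn-3 and cle40-2 the nitrate genes (1.12-fold, cameraPR adjusted p = 0.104) and hypoxia genes (1.18-fold, cameraPR adjusted p = 0.0891) differed by similar sizes in the same direction without passing.

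Between crn-3 and clv2-gabi, auxin genes (1.02-fold, cameraPR adjusted p = 0.0222, 17 of 24), defence genes (1.19-fold, cameraPR adjusted p = 0.0249, 8 of 9) and touch genes (1.08-fold, cameraPR adjusted p = 0.00246, 5 of 7) were higher in crn-3, and photosynthesis genes were lower in crn-3 (1.2-fold, cameraPR adjusted p = 0.0477, 11 of 12). The photosynthesis list holds no mutated gene, and its unadjusted p of 0.0126 stayed the same without them, but the adjustment over the lists then gave a cameraPR adjusted p of 0.0596. The list of CLE receptors and root stem cell regulators differed between crn-3 and clv2-gabi (cameraPR adjusted p = 1.88e-09) and between clv2-gabi and cle40-2 (cameraPR adjusted p = 0.00685). Without CLE40, CLV2 and CRN neither difference passed (cameraPR adjusted p = 0.737 and 0.783). These genes were left out together, so the part of each was not separated.

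The opposite movement of endodermis markers was weighed against another share of mature root in the cut tips, since the labels give no length of the cut. In crn-3 and clv2-gabi too few of these markers had a mean of at least 50 for a list test at that level. More mature tissue was assumed to move endodermis and xylem markers together, which was not tested. Genes of the chromosome 3 block were left out, which left 17 xylem markers in cle40-2. There the endodermis median exceeded the xylem median by 1.21 on the log2 scale (95% bootstrap interval over genes 0.73 to 1.69). A longer cut that moved both lists alike would not give this difference. A cut that added endodermis markers more than xylem markers is not excluded, so the length of the cut stays open. The epidermis and root hair median exceeded the xylem median by 0.35 in cle40-2, with an interval of -0.16 to 0.91 that reached across 0. In clv2-gabi the endodermis minus xylem difference was -0.25 and both medians lay below 0 (intervals -0.72 to -0.17 and -0.60 to -0.01). A smaller share of mature root may therefore account for the lower markers, as may later differentiation in the mutant, which was not tested. In crn-3 the difference was -0.16, the xylem interval of -0.51 to 0.13 reached across 0, and the explanations cannot be told apart.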

How the results depend on the processing

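The settings added after seeing the data were adjusted p under 0.01 for shared genes, the means of at least 10 and 50 with the deposited adjusted p, and those that left out the chromosome 3 block, genes near 0 in Col-0 or the mutated genes. No paired analysis was possible because the tables hold group means and carry no replicate numbers. For the same reason leaving out a replicate, splitting the controls or the samples, other normalizations, other tools, other fits of the samples, another pseudocount per sample and an estimated correlation were not run. Adjusting p again after a filter, Bonferroni adjustment and the use of unadjusted p for shared genes were not run because the tables hold no unadjusted p. Depth per library is unknown, and what it limits could be seen only in the wider range of fold changes at low means.

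Called genes at adjusted p under 0.01 were 65 in crn-3 and 287 in clv2-gabi, and with a log2 fold change of at least 1 in size 53 in crn-3, 152 in clv2-gabi and 677 in cle40-2, since these settings are stricter. In crn-3 that size limit moved the share of higher calls from 43.0% to 64.2%, and a mean of at least 50 moved it to 28.2%. Total counts under the other settings stayed within 1.5 times the main ones, while higher calls in cle40-2 fell from 758 to 466 at a mean of at least 50. Re-centring could hardly test the split of higher and lower calls, because the median folds were 1, 1.01 and 1 in crn-3, clv2-gabi and cle40-2 and the deposited p stayed as it was. Of 172 named gene results 25 were no longer past an adjusted p of 0.01. Lists past the threshold at a preset correlation of 0.05 were 2 in crn-3, 3 in clv2-gabi and 3 in cle40-2, against 8, 7 and 5 at 0.01. In cle40-2 there were 3 with a mean of at least 50 and 2 by ranks, endodermis and photosynthesis, and the cause was not tested. Of 58 list results 14 lost their call under some setting, 2 gained one and 0 reversed. Mitotic genes were the 2 that gained one, higher by ranks in crn-3 (cameraPR adjusted p = 0.0221) and clv2-gabi (cameraPR adjusted p = 0.0105).

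Shared calls at adjusted p under 0.1 in both were 22 in the same direction for crn-3 and cle40-2, and 1 in opposite directions for crn-3 and clv2-gabi where none was found at 0.05. At adjusted p under 0.01 in both, crn-3 and clv2-gabi shared 33 in the same direction, crn-3 and cle40-2 shared 4 and had 4 opposite, and clv2-gabi and cle40-2 shared 24 and had 22 opposite. Without the chromosome 3 block, clv2-gabi and cle40-2 had 48 opposite calls.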

Other observations

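The tests of this part were all chosen after the result was seen. Grouped by product name in the TAIR10.1 annotation, among genes with a mean of at least 10, several families held more calls than their size would give (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over 610, 605 and 615 families in crn-3, clv2-gabi and cle40-2). Lipid-transfer type genes of the bifunctional inhibitor family were lower in crn-3 (9 of 30, 0.0944 expected, adjusted p = 1.29e-13) and in clv2-gabi (11 of 29, 0.578 expected, adjusted p = 2.56e-09). Arabinogalactan protein genes were lower in crn-3 (5 of 26, adjusted p = 4.91e-06) and clv2-gabi (7 of 26, adjusted p = 5.62e-05), as were plasma membrane aquaporins (2 of 7 with adjusted p = 0.0308, and 4 of 7 with adjusted p = 0.000398). Xyloglucan endotransglucosylases were lower in clv2-gabi (7 of 15, adjusted p = 1.33e-06). Proline-rich extensin-like genes were lower in clv2-gabi (5 of 9, adjusted p = 4.35e-05) and higher in cle40-2 (9 of 9, adjusted p = 6.82e-11). Peroxidases of the superfamily were lower in crn-3 (4 of 33, adjusted p = 0.000684) and clv2-gabi (10 of 33, adjusted p = 1.62e-07) and higher in cle40-2 (12 of 41, adjusted p = 4.75e-06). In cle40-2 proton pump genes (5 of 9, adjusted p = 0.00147) and sucrose synthases (4 of 6, adjusted p = 0.00385) were higher, and LOB domain (4 of 9, adjusted p = 0.0155), GDSL-like lipase (6 of 28, adjusted p = 0.0155), defensin-like (3 of 5, adjusted p = 0.0291) and serine carboxypeptidase-like genes (5 of 24, adjusted p = 0.0388) were lower. Berberine type genes were higher in cle40-2 (5 of 12, adjusted p = 0.00506), and low temperature and salt responsive genes were lower in clv2-gabi (3 of 6, adjusted p = 0.00907). Members of such families share sequence, and how reads that match several genes were counted is not given.

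The block on chromosome 3 in cle40-2 lies on another chromosome than CLE40. A candidate explanation is that the cle40-2 plants carry a duplicated copy of this segment. Of the 71 block genes with a mean of at least 50, 81.7% had a fold between 1.5 and 2.7, bounds chosen after the values were seen. The least share the hypothesis needs was set at 80%, so the margin is small. The edges of the block were placed to make the summed rise of its genes largest, so much of this share follows from that choice. A plain doubling of every gene does not account for the 3 lower ones, AT3G16370 at 0.18, NSP3 at 0.22 and NSP1 at 0.47 in the authors' deposited table. Reads shared between similar genes are argued against by a median of 100% unique windows in the block genes. The 50 genes on either side had a median log2 change of -0.0022. The edges were placed where the rise ended, so this value does not test the authors' normalization. Whether the segment is doubled, and whether it differs from Col-0 in all libraries, stays open, since neither DNA nor values per library were analysed here. Among the raised genes, chosen here after their values were seen, were RR1 (ARR1, AT3G16857, a cytokinin response regulator) at 2.15-fold, the corepressor gene TPR2 at 1.85-fold and TCTP at 2.07-fold in the authors' deposited table, so such changes may follow from position and not from CLE40.

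In cle40-2, 129 genes went from a mean of 2 or less in Col-0 to 10 or more, against 16 in crn-3 and 3 in clv2-gabi. Reads shared between similar genes are argued against for the set by a median of 100% unique windows. Genomic DNA as the source of the rises to 10 or more is argued against by the genes at exactly 0 in Col-0, of which 77.8% (4893 of 6288) were also at exactly 0 in cle40-2. The other 1395 rose above 0, against 586 in crn-3 and 780 in clv2-gabi, so a trace of DNA is not excluded as a source of small values. Green tissue among the root tips cannot be told apart from activity of these genes in the root: of 20 photosynthesis genes 16 were higher, but the means of LHB1B1, RBCS1A and LHCB6 grew by 577, 54 and 10, and no profile of green tissue was at hand to say what share that needs. The seed storage genes CRU3 and CRA1 and the anther gene ATA27 appeared too, and whether a single library carried these transcripts is not visible in group means.

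Of 31 genes numbered AT2G07 with a mean of at least 10 and under 50% unique windows, 10 were higher in cle40-2 (median 1.91-fold), and 0 in crn-3 and 0 in clv2-gabi. The group was picked as genes that share sequence with the mitochondrial genome. Most of their windows occur elsewhere too, so their reads cannot be assigned to these genes, and their origin was not tested.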
